A study of Mus musculus with 30 samples.

How the data were processed

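The series holds 30 Affymetrix whole-genome mouse arrays from CD11b+ cells in 10 groups of 3. The cells were taken by immunomagnetic enrichment from healthy spleens of BALB/c and C57BL/6 mice, from the spleens and tumors of mice carrying C26-GM, from 4T1, EL-4 and MCA203 tumors, from fresh BALB/c bone marrow, and from bone marrow kept for 4 days with GM-CSF and either IL-6 or G-CSF. C26-GM is, per the labels, a colon carcinoma that makes GM-CSF. Total RNA was extracted with Trizol and cleaned on RNeasy columns, and the labelling was with biotin.

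The deposited table was used as it stands. Its values are log2 RMA expression per the labels and the authors' processing notes, and the version of RMA is not given in the sources used here. Across arrays the lowest value lay between 1.68 and 1.90, the highest between 13.9 and 14.5 and the median between 4.85 and 5.15, a range that a log2 scale gives and that raw intensities do not. Correlations between arrays of one group ran from 0.941 to 0.995. The scanner files were not used here, so the background correction and the scan date were not varied.

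Of 45101 probe sets, 34958 carried 1 gene symbol in the annotation used, 932 carried several and 9211 carried none. Of those with 1 symbol, 34754 (99.4%) were found in a RefSeq gene table, and 0 symbols had to be updated. Each gene was represented by its probe set with the highest mean over all arrays, which left 18194 genes. Of these genes 9012 had more than 1 probe set, and where probe sets of a named gene moved in opposite directions by more than 0.5 log2 both values are printed. A second probe set nearer to no change is printed only for a few examples.

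All 30 arrays and 10 groups entered 1 linear model in limma (R 4.3.3, limma 3.58.1), with moderated t statistics and Benjamini-Hochberg adjustment within each comparison. A gene was called changed at adjusted p below 0.05 with at least a 2-fold change, which is 1 on the log2 scale. Changes are log2 differences with their standard errors, every group has n = 3 arrays, and levels are group means with standard deviations. The standard errors rest on 1 estimate of the spread per gene over all 10 groups, not on the compared arrays alone. They can understate the spread of groups that vary more than the others. Figures were drawn with Python 3.11.15. Healthy spleen of the same strain was the reference for tumor-induced cells, and fresh marrow was the reference for the cultures. Cells from tumors had no reference other than spleen, so what is called a tumor effect also holds the difference in organ. The difference between strains was the mean effect of the C57BL/6 models less the mean effect of the BALB/c tumor models.

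The comparisons, the calling rule, the 23 gene lists, the fixed panel of 19 genes and the processing alternatives listed first below were set before the data were examined. The lists were written from general knowledge of myeloid biology and of the cell types that could come along with CD11b+ cells. Each list was tested against all other genes with camera in limma at its preset inter-gene correlation of 0.01, and again with a correlation estimated from the arrays. The 276 list tests formed 1 family for the adjustment. Beside the number of list members that passed over all genes, the number that passed when adjusted over the list alone is given where it differs. Some genes stand in several lists, Chil3, Vegfa and Mrc1 among them. Members not measured by a probe set with 1 symbol included Cebpe, Prss57, Ly6g, Retnlg, Stfa2, Ly6c1, Ly6c2, H2-DMb1, Clec9a, Ccnb1, Eno1, Isg15, Ifi44, Spp1, Lck, Klrb1c, Hbb-b1, Ahsp and Prss34. Some further list members are not reported here.

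The genes named for each comparison were those with the largest rises and falls among changed genes whose replicate values did not overlap, 8 each way, or 5 each way for the strain, interaction, culture against culture and tumor against spleen comparisons. Predicted and unnamed transcripts were passed over. The fixed panel, H2-Ea, and up to 4 changed members of each list with the largest changes were added. With 3 arrays a side, non-overlap arises by chance in 10% of genes.

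The alternatives set beforehand were centring each array on the mean of 10 measured housekeeping genes, quantile normalisation again over the compared arrays, a model with only the compared groups, array weights, removal of genes whose highest group mean lay under the 40th percentile (14867 genes left), the mean of all probe sets of a gene, removal of probe sets that may cross-hybridise (17904 genes left), a trended and robust variance prior, adjusted p below 0.01, no minimum fold change, a replicate block, leaving out each array in turn, and, for gene lists, the estimated correlation and the rotation test fry. The alternatives added after seeing the data were a term for the culture array set (fresh marrow coded with the wide arrays), the narrow culture arrays only, the wide culture arrays only, the model without the third C26-GM arrays, and a covariate for the 3' less 5' signal of actin. Where a single array was left in a group, its spread was assumed to equal that of the other groups.

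The gene and list tests were tried on simulated changes, added for the gene tests to 100 genes of each size. Genes moved by 3 log2 were called in 100% of cases in every comparison, and those moved by 1.5 log2 in 76% to 100%, with 0 to 6 false calls among 18194 genes. With camera a shifted gene list was found at an adjusted p of 1.84e-53, with 0 other lists called, in a single draw. The simulated genes were independent of one another and held no culture array sets. This trial therefore does not test list calls that arise from correlation between genes.

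The labels do not say whether the arrays of a group came from separate animals, so the p values measure only the spread between arrays of a group, pooled over all 10 groups. The number of arrays limits the precision of every estimate.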

Results

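CD11b+ cells from the spleens of C26-GM bearing mice (n = 3) differed from those of healthy BALB/c spleens (n = 3) in 1118 of 18194 genes, of which 422 rose and 696 fell. The largest rises were Rnase2a, an eosinophil-associated ribonuclease (log2 change 6.94 ± 0.46), Dmkn, or dermokine (6.17 ± 0.33), the Y-linked Eif2s3y (6.02 ± 0.14), the endothelial lipase Lipg (5.61 ± 0.37) and coagulation factor F7 (5.31 ± 0.24). Next came the carbonic anhydrase Car4 (5.23 ± 0.31), the matrix proteoglycan Vcan (4.74 ± 0.40) and the serine protease Htra3 (4.62 ± 0.29). The largest fall was that of Xist, the RNA that silences an X chromosome (-5.40 ± 0.21). Xist lay between 5.15 and 6.47 on the 6 C26-GM arrays and between 10.06 and 11.12 on the other 24. Further falls were those of the eosinophil granule protein Prg2 (-5.11 ± 0.43), the granzyme Gzma (-4.66 ± 0.34) and the sialyltransferase St8sia6 (-4.48 ± 0.31). They also took in the ubiquitin-like Ubd (-4.37 ± 0.36), the IgM receptor Fcmr (-4.28 ± 0.22), Cd83 (-4.27 ± 0.33) and the phosphatidylserine receptor Timd4 (-4.08 ± 0.27). Of genes tied to suppressive myeloid cells, Cebpb, a transcription factor of emergency granulopoiesis, rose (1.65 ± 0.17, adjusted p = 8.4e-08), as did the IL-4 receptor chain Il4ra (1.45 ± 0.31). The prostaglandin synthase Ptgs2 (-2.94 ± 0.50) and the macrophage marker Adgre1 (-1.24 ± 0.20) fell. Arginase 1, Arg1, did not pass (0.30 ± 0.35, adjusted p = 0.65), nor did the nitric oxide synthase Nos2 (0.20) or the calgranulins S100a8 (0.18) and S100a9 (0.07).

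Of 11 measured primary granule genes, which mark immature granulocytes, 7 rose and 0 fell in this spleen (median 1.89, adjusted p = 5.11e-07, and adjusted p = 0.0973 with an estimated correlation). They were led by the granule enzymes Mpo (3.72 ± 0.39), Ctsg (3.39 ± 0.37) and Prtn3 (2.80 ± 0.33) and by Ms4a3 (2.68 ± 0.37). Of 17 later granule genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.84, adjusted p = 0.00151, and adjusted p = 0.389 with an estimated correlation). Wfdc21 rose by 2.47, Mmp8 by 2.28 and Chil3 by 2.18. Cell cycle genes rose in 8 of 22 cases, with 0 falls (median 0.87, adjusted p = 9.65e-10, and adjusted p = 0.232 with an estimated correlation). Among them were Mki67 (1.48) and Cdk1 (1.23), and 14 rose without the third C26-GM arrays. Alternative activation genes gave 7 rises and 2 falls among 12 (median 1.61, adjusted p = 0.00157, and adjusted p = 0.0914 with an estimated correlation). They ran from the chemokine Ccl17 (3.51) and the cadherin Cdh1 (3.40) to the lipoxygenase Alox15 (-2.51).

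Interferon-stimulated genes fell in 12 of 16 cases, with 0 rises (median -1.95, adjusted p = 5.64e-16), including Ifit3 (-3.01), Usp18 (-2.61) and Mx1 (-2.60). Monocyte and macrophage genes gave 1 rise and 7 falls among 18 (median -0.88, adjusted p = 2.05e-08), with the fractalkine receptor Cx3cr1 at -3.11 and the lipid carrier Apoe at -1.53. Markers of lymphocytes fell beside them. These were 9 of 10 for B cells, such as Ms4a1 (-3.48) and Cd79b (-3.42; median -2.08, adjusted p = 3.5e-18). They were 8 of 8 for NK cells (median -2.11, adjusted p = 5.85e-15, Klrd1 -4.07) and 4 of 11 for T cells (median -0.81, adjusted p = 3.06e-06, Cd28 -1.88). Markers of mast cells, basophils and eosinophils gave 1 rise and 4 falls among 10 (median -0.74, adjusted p = 5.51e-05, and adjusted p = 0.0966 with an estimated correlation), with Prg2 at -5.11 and the eotaxin receptor Ccr3 at -3.23. Erythroid markers fell in 3 of 7 cases (median -0.82, adjusted p = 0.0016, and adjusted p = 0.244 with an estimated correlation). Platelet and megakaryocyte markers rose in 3 of 9 (median 0.63, adjusted p = 0.00139, and adjusted p = 0.246 with an estimated correlation), led by Ppbp (2.87). Antigen presentation genes fell in 5 of 15 cases (median -0.42, adjusted p = 2.37e-06, and adjusted p = 0.0618 with an estimated correlation). The homing receptor Ccr7 fell by 3.59 and the costimulator Cd86 by 2.05. Matrix remodelling genes (6 rises and 1 fall among 13, median 0.54, adjusted p = 5.63e-05, and adjusted p = 0.117 with an estimated correlation) included Mmp19 (4.32) and the plasminogen activator Plau (3.93). Hypoxia and glycolysis genes (4 rises among 18, median 0.77, adjusted p = 2.56e-05, and adjusted p = 0.268 with an estimated correlation) included Pfkp (1.91) and Pgam1 (1.44). Immunosuppressive effectors did not pass (1 rise and 3 falls among 18, or 2 and 3 adjusted over the list alone, median 0.13, mean -0.06, adjusted p = 0.736). With housekeeping centring 25.6% of the changed genes rose, against 37.7% without it.

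In the C26-GM tumor itself 2073 genes changed against healthy spleen, 775 up and 1298 down (n = 3 and 3). Cxcl3, a neutrophil-attracting chemokine, rose most (9.80 ± 0.21), followed by Car4 (7.64 ± 0.31), Dmkn (7.43 ± 0.33) and Arg1, which depletes arginine (6.78 ± 0.35, adjusted p = 2.2e-14). Behind them were Rnase2a (6.66 ± 0.46), Eif2s3y (6.51 ± 0.14), Lipg (6.44 ± 0.37) and the endocytic adaptor Dab2 (6.29 ± 0.26). The largest falls were those of the immunoglobulin joining chain Jchain (-8.00 ± 0.41), the prostaglandin-degrading enzyme Hpgd (-7.56 ± 0.32), Igha (-7.33 ± 0.41) and the adhesion receptor Vcam1 (-7.32 ± 0.34). They continued with Adgre4 (-7.00 ± 0.31), Ighm (-6.72 ± 0.20), H2-Ob (-6.43 ± 0.30) and Cd5l (-6.31 ± 0.33). The probe sets of Ighm ran from -7.49 to 1.0. Cebpb (2.62 ± 0.17), Ptgs2 (1.97 ± 0.50), Il4ra (1.93 ± 0.31) and the angiogenic factor Vegfa (1.39 ± 0.38) rose. Irf8, a regulator of monocyte fate (-1.11 ± 0.26), the NADPH oxidase subunit Cybb (-1.56 ± 0.19) and Adgre1 (-2.64 ± 0.20) fell. Nos2 (0.64), S100a8 (0.09) and S100a9 (-0.02) did not pass. Without the third C26-GM arrays, of which the tumor one had an actin 3' less 5' signal of 2.42, 2038 genes changed.

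Of 18 immunosuppressive effectors 8 rose and 1 fell in the C26-GM tumor (median 0.78, adjusted p = 0.000251). The ectonucleotidase Nt5e (3.88) and the arginine transporter Slc7a2 (2.84) rose, while the heme oxygenase Hmox1 fell (-2.09). Inflammatory cytokines and chemokines rose in 12 of 18 cases and fell in 2 (median 1.87, adjusted p = 2.03e-07), with Cxcl2 at 5.13, Il6 at 4.38 and Osm at 4.37. Matrix remodelling genes gave 10 rises among 13 (median 2.51, adjusted p = 1.36e-09), with thrombospondin Thbs1 at 5.38 and Mmp19 at 4.23. Hypoxia and glycolysis genes gave 14 rises among 18 (median 1.47, adjusted p = 8.43e-13, and adjusted p = 0.0559 with an estimated correlation). The oxygen sensor Egln3 rose by 3.49 and the glucose transporter Slc2a1 by 2.80. Monocyte and macrophage genes (2 rises, 11 falls, median -1.66, adjusted p = 1.4e-08) and antigen presentation genes (0 rises, 11 falls, median -1.44, adjusted p = 9.35e-13) both fell. Cx3cr1 fell by 4.31, complement C1qb by 3.20, the lectin Cd209a by 4.49 and Dpp4 by 3.98. Later granule genes were split between 5 rises and 4 falls, or 6 and 4 adjusted over the list alone (median 0.09, mean -0.16, adjusted p = 0.994). Mmp8 (2.68) and Wfdc21 (2.63) rose, and Ltf (-4.34) and Camp (-5.45) fell. Markers of B cells fell in 9 of 10 cases (median -2.77, adjusted p = 2.63e-14) and those of NK cells in 7 of 8 (median -1.97, adjusted p = 9.18e-09). T cell markers fell in 5 of 11 (median -0.81, adjusted p = 8.23e-05, and adjusted p = 0.066 with an estimated correlation). NADPH oxidase genes gave 1 fall among 5 (median -0.69, adjusted p = 0.0356, and adjusted p = 0.428 with an estimated correlation).

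Cells from 4T1 tumors differed from healthy BALB/c spleen cells in 2231 genes, 1242 up and 989 down. Arg1 led (8.92 ± 0.35, adjusted p = 2.1e-16), ahead of Cxcl3 (8.47 ± 0.21), the monocyte chemokines Ccl12 (7.99 ± 0.36) and Ccl8 (7.44 ± 0.33). After these came Dab2 (6.38 ± 0.26), Moxd1 (6.27 ± 0.31), Nt5e (6.18 ± 0.34) and the collagenase Mmp13 (6.04 ± 0.47). The largest falls were those of Hpgd (-7.05 ± 0.32), Jchain (-6.91 ± 0.41), Igha (-6.70 ± 0.41), and the immunoglobulin segments Iglv1 (-6.16 ± 0.38) and Igkv8-30 (-6.15 ± 0.33). They were followed by Cd5l (-5.87 ± 0.33), H2-Ob (-5.54 ± 0.30) and Spic, a factor of red pulp macrophages (-5.43 ± 0.21). Vegfa (3.66 ± 0.38), Ptgs2 (3.26 ± 0.50), Il4ra (1.90), the cytokine Il10 (1.37 ± 0.24), the checkpoint ligand Cd274 (1.22) and Cebpb (1.09 ± 0.17) rose. Nos2 (0.53), S100a9 (-0.52) and S100a8 (-0.57) did not pass. With housekeeping centring the values of Cebpb (0.80) and Cd274 (0.94) lay below 2-fold. With it 35.6% of the changed genes rose, against 55.7%.

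Hypoxia and glycolysis genes rose in 17 of 18 cases in 4T1 (median 2.21, adjusted p = 4.43e-22), with Egln3 at 4.24 and Slc2a1 at 3.13. Matrix remodelling genes gave 11 rises among 13 (median 3.21, adjusted p = 3.57e-15), including the cathepsin Ctsk (5.26) and the membrane protease Mmp14 (4.41). Cytokines and chemokines gave 13 rises and 1 fall (median 3.14, adjusted p = 2.02e-15), including Ccl2 (5.82) and Ccl7 (5.59). Immunosuppressive effectors gave 10 rises and 1 fall (median 1.30, adjusted p = 8.45e-07), with Slc7a2 at 3.80. Cell cycle genes (13 rises among 22, median 1.15, adjusted p = 1.13e-10, and adjusted p = 0.201 with an estimated correlation) included the checkpoint kinase Bub1 (2.15). Cholesterol biosynthesis genes (6 rises, median 1.11, adjusted p = 2.24e-06, and adjusted p = 0.197 with an estimated correlation) included Sqle (2.33). Monocyte and macrophage genes gave 5 rises and 2 falls (median 0.55, adjusted p = 0.0273, and adjusted p = 0.261 with an estimated correlation). The lipid receptor Trem2 rose by 3.66 and Ace fell by 2.09. Later granule genes fell in 9 of 17 cases (median -1.08, adjusted p = 1.14e-07, and adjusted p = 0.141 with an estimated correlation). Camp fell by 3.56 and Ltf by 2.37. Antigen presentation genes fell in 7 of 15 cases (median -0.87, adjusted p = 3.09e-07) and B cell markers in 9 of 10 (median -2.71, adjusted p = 4e-15). NK markers fell in 7 of 8 (median -1.94, adjusted p = 5.63e-09) and T cell markers in 5 of 11 (median -0.90, adjusted p = 2.52e-06). Markers of other tissues rose beside these groups. They were 7 epithelial genes (median 2.62, adjusted p = 2.26e-06, and adjusted p = 0.149 with an estimated correlation), among them the keratins Krt18 (6.01) and Krt8 (5.96). Fibroblast genes gave 7 rises and 1 fall (median 1.32, adjusted p = 1.69e-05, and adjusted p = 0.118 with an estimated correlation), among them the collagen Col3a1 (5.36).

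In EL-4 tumors 1968 genes changed against healthy C57BL/6 spleen, 1168 up and 800 down. The leading rises were Arg1 (8.13 ± 0.35, adjusted p = 1.1e-15), Ccl8 (7.50 ± 0.33), the glycoprotein Gpnmb (6.74 ± 0.27) and the proton pump subunit Atp6v0d2 (6.52 ± 0.49). Next were the hyaluronan receptor Lyve1 (6.33 ± 0.41), the interferon Ifng (6.23 ± 0.24), Col3a1 (6.20 ± 0.52) and Glycam1 (5.94 ± 0.62). The largest falls were those of the granule protein genes Camp (-8.00 ± 0.31) and Ngp (-7.44 ± 0.38), followed by Hpgd (-5.10 ± 0.32), H2-Q10 (-4.91 ± 0.19) and the calgranulin S100a9 (-4.85 ± 0.15). Igha (-4.61 ± 0.41) and the granule genes Ltf (-4.57 ± 0.49) and Lcn2 (-4.50 ± 0.44) came next, and S100a8 fell by 4.41 ± 0.14. Nos2, which makes nitric oxide, rose (2.93 ± 0.29, adjusted p = 1.6e-08), as did Il10 (3.14 ± 0.24), Ptgs2 (3.07 ± 0.50), Vegfa (2.16), Cd274 (1.52), Il4ra (1.36) and Irf8 (1.05, or 0.69 with housekeeping centring). Cebpb lay below 2-fold (0.88 ± 0.17, adjusted p = 0.00033).

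Later granule genes fell in 14 of 17 cases in EL-4, or 15 adjusted over the list alone (median -4.25, adjusted p = 5.16e-26). Immunosuppressive effectors gave 12 rises and 1 fall (median 1.84, adjusted p = 1.55e-09; Slc7a2 3.55). Cytokines and chemokines gave 11 rises (median 2.08, adjusted p = 9.51e-13), including Ccl12 (5.90), Ccl2 (5.68) and Cxcl2 (5.61). Matrix remodelling genes gave 9 rises (median 3.13, adjusted p = 1.51e-14; Ctsk 5.65, Mmp12 4.48). Hypoxia and glycolysis genes rose in 16 of 18 cases (median 1.96, adjusted p = 3.34e-18; Egln3 3.08, Pfkl 3.02). Alternative activation genes gave 8 rises and 1 fall (median 1.83, adjusted p = 9.77e-05), including Egr2 (3.32), the lectin Mgl2 (3.24) and Ccl24 (2.99). T cell markers rose in 6 of 11 cases (median 1.38, adjusted p = 6.68e-07), among them Cd28 (3.15), Cd3g (2.96) and Cd8b1 (2.94). B cell markers fell in 8 of 10 (median -1.55, adjusted p = 7.41e-10). NK markers did not pass as a group (median 0.46, adjusted p = 0.124). They held 3 rises, Prf1 (2.18), Gzma (1.27) and Eomes (1.17), and 1 fall, Klrd1 (-1.08). Fibroblast markers gave 8 rises (median 1.84, adjusted p = 2.74e-08). Epithelial markers gave 7 (median 1.63, adjusted p = 7.86e-05, and adjusted p = 0.234 with an estimated correlation, Krt19 5.16) and endothelial markers 4 (median 0.91, adjusted p = 0.0252, and adjusted p = 0.471 with an estimated correlation). Antigen presentation genes had a median of 0.00, a mean of -0.61 and 4 falls (adjusted p = 0.0191, and adjusted p = 0.363 with an estimated correlation). With housekeeping centring 29.1% of the changed genes rose, against 59.3%.

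MCA203 tumors gave 1897 changed genes against the same spleens, 911 up and 986 down. The largest rises were the chemokines Ccl12 (7.08 ± 0.36) and Ccl8 (6.96 ± 0.33), the granzyme Gzmd (6.91 ± 0.27), Arg1 (6.81 ± 0.35, adjusted p = 2.2e-14) and Ccl7 (6.45 ± 0.28), then Dab2 (6.43 ± 0.26), the interferon-induced GTPase Gbp2b (6.37 ± 0.31) and Col3a1 (6.17 ± 0.52). The largest falls were Camp (-7.74 ± 0.31), Ngp (-7.30 ± 0.38), Lcn2 (-7.16 ± 0.44), Igha (-6.63 ± 0.41), Jchain (-6.50 ± 0.41), Cd5l (-6.38 ± 0.33), Ltf (-6.35 ± 0.49) and the B cell marker Ms4a1 (-6.30 ± 0.37). Ptgs2 (2.55), Il10 (2.37 ± 0.24), Vegfa (2.29) and Il4ra (1.14, or 0.89 with housekeeping centring) rose. S100a9 (-4.38 ± 0.15) and S100a8 (-4.17 ± 0.14) fell. Cd274 (0.77, adjusted p = 0.016), Nos2 (0.58) and Cebpb (-0.16 ± 0.17) were not called.

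Later granule genes fell in 17 of 17 cases in MCA203 (median -4.17, adjusted p = 2.76e-36). Cell cycle genes gave 17 rises among 22 (median 1.30, adjusted p = 5.78e-13, and adjusted p = 0.151 with an estimated correlation, Cdk1 2.24). Hypoxia and glycolysis genes gave 13 rises (median 1.34, adjusted p = 6.3e-11, and adjusted p = 0.0773 with an estimated correlation, Tpi1 2.41). Cytokines and chemokines gave 10 rises (median 1.04, adjusted p = 1.04e-10; Ccl2 6.13, Cxcl3 5.51). Interferon-stimulated genes rose in 7 of 16 cases, or 8 adjusted over the list alone (median 1.04, adjusted p = 5.98e-05, and adjusted p = 0.28 with an estimated correlation). The chemokines Cxcl9 and Cxcl10 rose by 3.91 and 3.24. Matrix remodelling genes gave 8 rises (median 1.94, adjusted p = 1.52e-06, and adjusted p = 0.0632 with an estimated correlation, Mmp13 5.78). Fibroblast markers rose beside them in 7 of 11 cases (median 1.13, adjusted p = 1.89e-05, and adjusted p = 0.12 with an estimated correlation), with Col3a1 at 6.17 and Col1a2 at 2.28. Epithelial markers did not pass as a group (median 0.42, adjusted p = 0.155), though Krt8 (4.51) and Krt18 (3.07) rose. Immunosuppressive effectors gave 6 rises and 2 falls (median 0.85, adjusted p = 0.00331, and adjusted p = 0.114 with an estimated correlation). They ran from galectin Lgals1 (2.70) to the second arginase Arg2 (-3.02). T cell markers gave 7 rises and 1 fall (median 1.41, adjusted p = 8.92e-06), with Cd3g at 4.03 and Cd8b1 at 3.46. NK markers gave 3 rises (median 0.58, adjusted p = 0.00576, and adjusted p = 0.347 with an estimated correlation), led by perforin Prf1 (3.44). B cell markers fell in 9 of 10 cases (median -3.0, adjusted p = 6.08e-20). C/EBP, STAT and other myeloid transcription factors gave 3 falls among 14 (median -0.37, adjusted p = 0.00428, and adjusted p = 0.432 with an estimated correlation). Among these Irf4 fell by 2.07. With housekeeping centring 29.6% of the changed genes rose, against 48.0%.

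**Figure D1:**
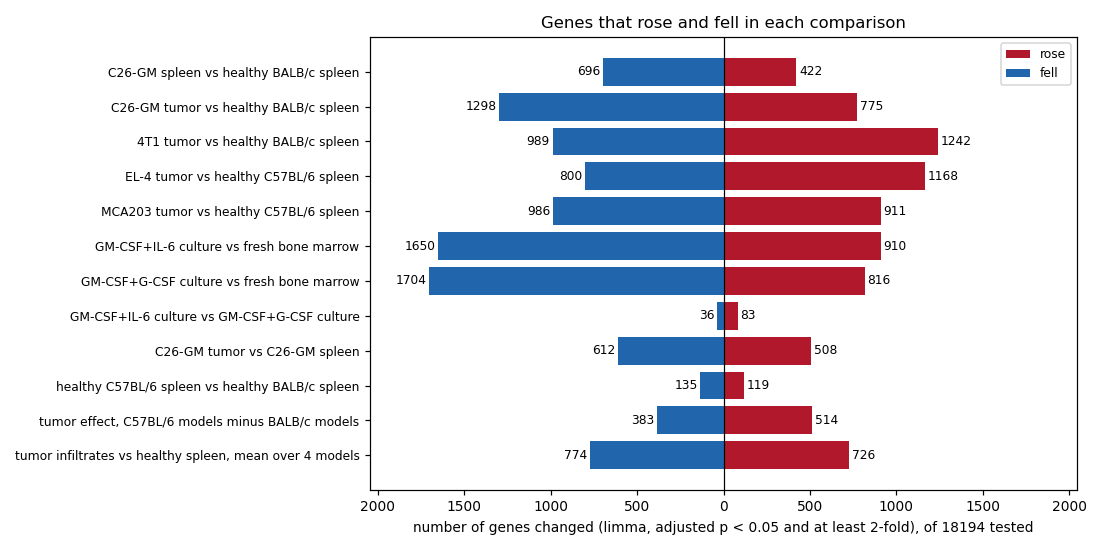
Genes that rose (right) or fell (left) in each of the 12 comparisons, among 18194 genes tested, at adjusted p below 0.05 and at least a 2-fold change.

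**Figure D2:**
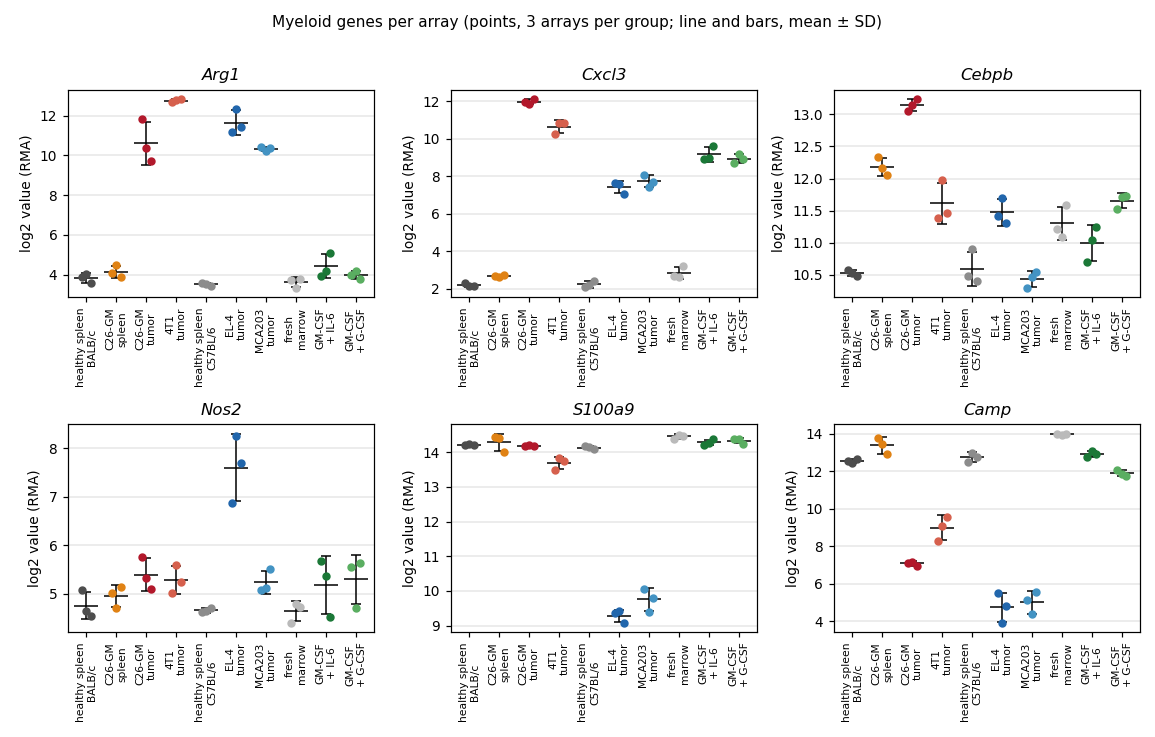
Log2 expression of Arg1, Cxcl3, Cebpb, Nos2, S100a9 and Camp on each of the 30 arrays. Points are arrays, and lines with bars are the mean and standard deviation of n = 3.

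Across the tumor models 440 genes changed in the same direction in all 4, of which 174 rose and 266 fell, against 0.17 and 0.168 for independent lists. Simulation without a tumor effect but with shared controls gave at most 0 such genes in 20 draws. It held no changed genes, so its count was near 0 in advance and does not gauge the excess. Independent lists leave out the control shared by the 2 models of a strain. Each reference has only 3 arrays, so it could not be split to remove the sharing, and part of the excess may come from the shared controls. The 2 strains had separate references. Both BALB/c tumor models shared 347 rises and 556 falls, and both C57BL/6 models 512 and 575. All 4 tumor groups were set against spleen only, so tumor and organ of origin cannot be told apart. That limit covers these shared changes and the mean over the 4 models. By mean change the shared rises were Arg1 (7.66 ± 0.21), Cxcl3 (7.25 ± 0.13), Ccl8 (6.37 ± 0.20), Ccl12 (6.22 ± 0.22) and Dab2 (6.15 ± 0.16). Below them stood Cxcl2 (5.16 ± 0.23), Ccl2 (5.11 ± 0.20) and the collagen Col3a1 (4.92 ± 0.32). The shared falls were Hpgd (-6.48 ± 0.20), Igha (-6.32 ± 0.25), Camp (-6.19 ± 0.19), Jchain (-5.71 ± 0.25), Cd5l (-4.90 ± 0.20), Ngp (-4.82 ± 0.23), Iglv1 (-4.79 ± 0.23) and St8sia6 (-4.73 ± 0.19). Rises seen in 3, 2 or 1 of the models numbered 319, 549 and 1345, and falls 340, 491 and 1007. With housekeeping centring the count was 496, of which 27.0% rose, against 39.5%.

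The mean over the 4 models changed in 1500 genes, 726 up and 774 down (housekeeping centring 31.1% up, against 48.4%). Cytokines and chemokines gave 13 rises and 1 fall in this mean (median 2.06, adjusted p = 2.23e-12) and matrix remodelling genes 10 rises (median 2.79, adjusted p = 1.83e-12). There were 15 rises for hypoxia and glycolysis genes (median 1.72, adjusted p = 4.37e-18) and 11 rises and 1 fall for immunosuppressive effectors (median 1.28, adjusted p = 1.06e-06). Later granule genes fell in 16 of 17 cases (median -2.02, adjusted p = 2.28e-20), B cell markers in 9 of 10 (median -2.60, adjusted p = 2.33e-16) and antigen presentation genes in 6 of 15 (median -0.62, adjusted p = 9.75e-08). Markers of mast cells, basophils and eosinophils gave 4 falls (median -0.92, adjusted p = 8.25e-06, and adjusted p = 0.0666 with an estimated correlation). Erythroid markers gave 4 falls (median -1.07, adjusted p = 3.56e-05, and adjusted p = 0.118 with an estimated correlation). Fibroblast markers gave 6 rises (median 1.26, adjusted p = 1.43e-05, and adjusted p = 0.117 with an estimated correlation). Epithelial markers gave 5 (median 1.33, adjusted p = 0.000622, and adjusted p = 0.313 with an estimated correlation). Platelet and megakaryocyte markers (median 0.05, adjusted p = 0.662) and endothelial markers (median 0.26, adjusted p = 0.439) did not pass. Over all 276 list tests 167 passed with the preset correlation, and 56 of these held with an estimated correlation.

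**Figure D3:**
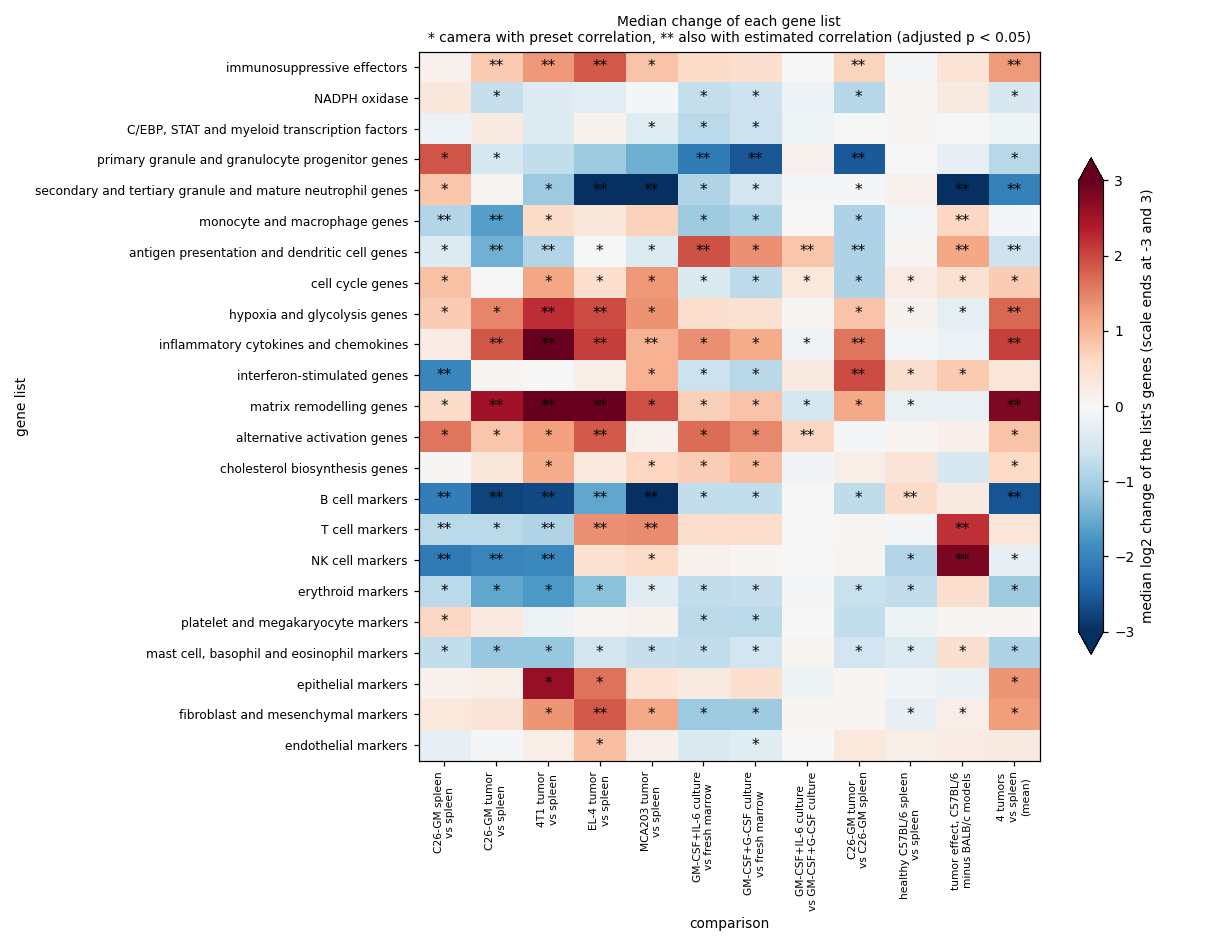
Median log2 change of each of the 23 gene lists in each of the 12 comparisons. Asterisks mark lists that passed with the preset correlation, and double asterisks those that also passed with an estimated one.

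C26-GM tumor cells and C26-GM spleen cells (n = 3 and 3) differed in 1120 genes, 508 higher and 612 lower in the tumor. Higher were Cxcl3 (9.30 ± 0.21), Arg1 (6.48 ± 0.35), the fatty acid carrier Fabp4 (5.29 ± 0.41), Ptgs2 (4.91 ± 0.50) and Ccl3 (4.71 ± 0.29). Lower were Vcam1 (-6.57 ± 0.34), Camp (-6.29 ± 0.31), Jchain (-5.52 ± 0.41), Ltf (-5.50 ± 0.49) and Cd5l (-5.47 ± 0.33). Cd274 rose (1.01 ± 0.23, or 0.82 with the actin covariate), Cybb (-1.89 ± 0.19) and Adgre1 (-1.41 ± 0.20) fell, and Cebpb lay below 2-fold (0.96 ± 0.17). Primary granule genes fell in 9 of 11 cases (median -2.52, adjusted p = 2.77e-14), with Mpo at -5.45 and Ctsg at -3.92. Cell cycle genes fell in 9 of 22 (median -0.92, adjusted p = 1.23e-10, and adjusted p = 0.201 with an estimated correlation). Interferon-stimulated genes rose in 12 of 16 cases (median 1.96, adjusted p = 5.96e-16, Ifit1 3.61). Cytokines and chemokines rose in 11 of 18 (median 1.61, adjusted p = 2.65e-17, Il6 4.15) and immunosuppressive effectors in 8 of 18 (median 0.66, adjusted p = 3.34e-08, Nt5e 3.12). Hypoxia and glycolysis genes gave 7 rises (median 0.86, adjusted p = 1.08e-10, and adjusted p = 0.0816 with an estimated correlation). Antigen presentation genes gave 7 falls (median -0.92, adjusted p = 1.04e-08). NADPH oxidase genes gave 2 falls among 5 (median -0.85, adjusted p = 0.000134, and adjusted p = 0.139 with an estimated correlation), one of them Ncf1 (-1.21). The third C26-GM tumor array had an actin 3' less 5' signal of 2.42, against 0.01 to 0.68 on the others. Without the third C26-GM arrays 1184 genes differed (528 up, 656 down), but the direction of the majority turned without the third tumor array alone (581 up, 540 down) and with the actin covariate (578 up, 543 down). With housekeeping centring 61.9% of the changed genes rose, against 45.4%.

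Healthy C57BL/6 and BALB/c spleen cells differed in 254 genes, 119 higher and 135 lower in C57BL/6. Higher were Trim12a (5.86 ± 0.15), the interferon-inducible Ifi213 (5.83 ± 0.25), H2-Q10 (5.79 ± 0.19), Nxpe4 (5.68 ± 0.18) and Rpgrip1 (5.65 ± 0.13). Lower were Ifi202b (-7.15 ± 0.36), Ifi44l (-6.87 ± 0.41), H2-Ea, a class II chain gene not expressed by C57BL/6 mice (-6.13 ± 0.22, adjusted p = 4.3e-17), Postn (-4.92 ± 0.26) and Gbp2b (-4.43 ± 0.31). No gene of the fixed panel passed (Arg1 -0.32 ± 0.35, Cebpb 0.07). B cell markers lay higher as a group though 0 of 10 passed singly (median 0.54, adjusted p = 8.61e-08). NK markers gave 1 rise and 2 falls (median -0.87, adjusted p = 0.000983, and adjusted p = 0.257 with an estimated correlation). Interferon-stimulated genes gave 1 rise, Oasl2 (2.59, median 0.47, adjusted p = 7.87e-05, and adjusted p = 0.29 with an estimated correlation).

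The tumor effect differed between the C57BL/6 models and the BALB/c models in 897 genes, 514 more positive and 383 more negative in C57BL/6. The most positive were the interferon Ifng (6.81 ± 0.29), the granzymes Gzmb (6.81 ± 0.31) and Gzma (6.15 ± 0.42), the lipase Lpl (6.45 ± 0.27) and Nkg7, a granule gene of killer lymphocytes that also stood in the primary granule list (5.84 ± 0.30). The most negative were the neutrophil genes Wfdc21 (-6.14 ± 0.37), Lcn2 (-6.05 ± 0.54), Ngp (-5.09 ± 0.47) and Stfa2l1 (-4.86 ± 0.46), along with H2-Q10 (-5.01 ± 0.24). H2-Q10 was also among the genes most above BALB/c in healthy C57BL/6 spleen, so a difference between the references enters its value. From the panel Adgre1 (2.06 ± 0.25), Il10 (1.97 ± 0.29), Irf8 (1.30 ± 0.31) and Nos2 (1.17 ± 0.36, adjusted p = 0.044) were more positive. The Nos2 difference comes from EL-4 (2.93), since MCA203 (0.58) lay near C26-GM tumor (0.64) and 4T1 (0.53). Cebpb (-1.49 ± 0.21), S100a8 (-4.05 ± 0.17) and S100a9 (-4.34 ± 0.18) were more negative, whereas Arg1 did not differ by this test (-0.38 ± 0.43, adjusted p = 0.80). For Cebpb the difference comes mainly from C26-GM tumor (2.62) and MCA203 (-0.16), since 4T1 (1.09) and EL-4 (0.88) lay close together. Later granule genes were more negative in 15 of 17 cases, or 16 adjusted over the list alone (median -3.38, adjusted p = 4.74e-42). T cell markers were more positive in 8 of 11 cases (median 2.19, adjusted p = 7.76e-22, Cd3g 5.58). NK markers were more positive in 7 of 8, or 8 adjusted over the list alone (median 2.83, adjusted p = 2.28e-20, Prf1 5.03). Antigen presentation genes gave 8 positive differences (median 1.15, adjusted p = 2.92e-07) and monocyte and macrophage genes 5 (median 0.62, adjusted p = 7.97e-06), including C1qb (2.47) and C1qa (2.28). In the monocyte and macrophage list the BALB/c models went opposite ways, with medians of -1.66 in C26-GM tumor and 0.55 in 4T1. The negative side of that difference thus comes from C26-GM. The BALB/c and C57BL/6 sets differ in tumor type as well as strain, the C26-GM arrays also differ from their reference in Xist (5.15 to 6.47 against 10.06 to 11.12 on all others), and Nos2 was not called with housekeeping centring. With that centring 40.7% of the changed genes were more positive, against 57.3%.

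**Figure D4:**
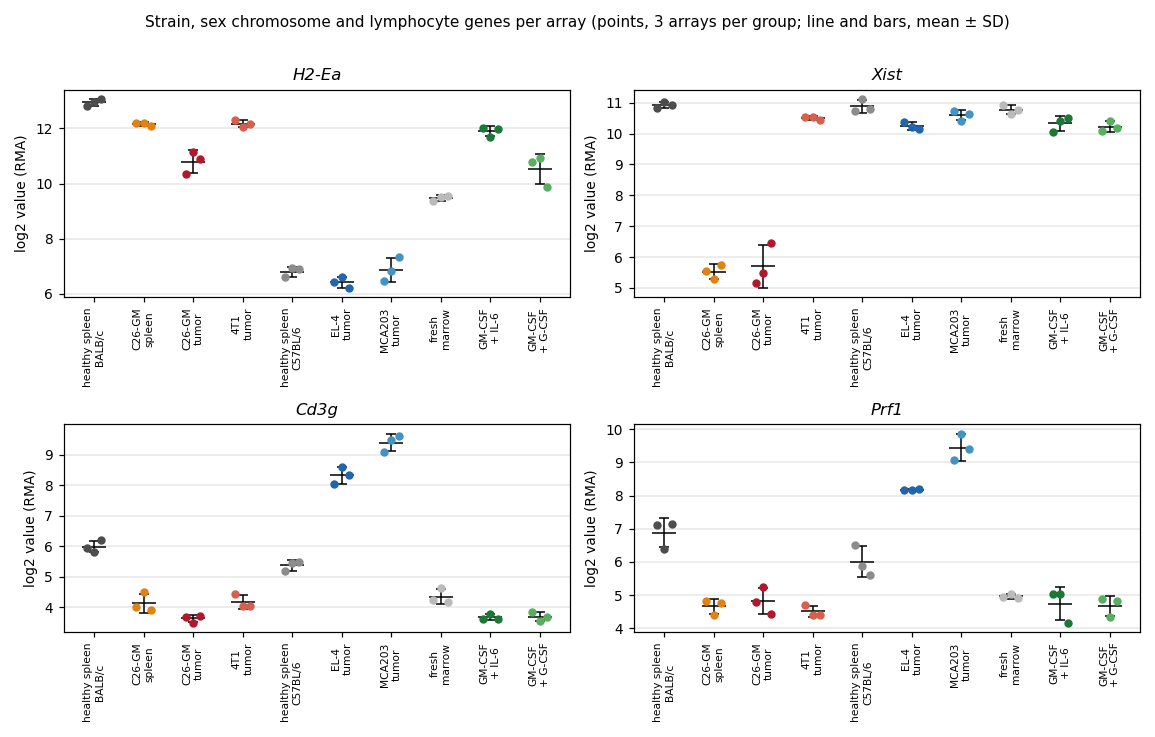
Log2 expression of H2-Ea, Xist, Cd3g and Prf1 on each of the 30 arrays. H2-Ea marks strain, Xist female sex, and Cd3g and Prf1 T cells and killer lymphocytes.

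Bone marrow kept with GM-CSF and IL-6 differed from fresh marrow (n = 3 and 3) in 2560 genes, 910 up and 1650 down. The metalloelastase Mmp12 rose most (8.59 ± 0.19), followed by Plet1 (7.75 ± 0.37), Ccn3 (7.05 ± 0.40) and the chemokine Ccl17 (6.95 ± 0.37). Then came the lectin Clec4n (6.64 ± 0.19), Cxcl3 (6.35 ± 0.21), Cdh1 (6.06 ± 0.47) and Car4 (4.98 ± 0.31). The largest falls were Vcam1 (-6.56 ± 0.34), Apoe (-5.91 ± 0.31), the adipocyte hormone Adipoq (-5.59 ± 0.16), Klra17 (-5.46 ± 0.39), the niche chemokine Cxcl12 (-5.23 ± 0.33), Orm1 (-5.11 ± 0.64), F13a1 (-5.08 ± 0.27) and C1qb (-5.07 ± 0.23). The probe sets of Cxcl12 ran from -5.23 to 0.58. Cd274 (3.07 ± 0.23), Adgre1 (1.89) and Tgfb1 (1.46) rose, and Ptgs2 (-4.23 ± 0.50) and Stat3 (-1.41) fell. Arg1 did not pass (0.79 ± 0.35, adjusted p = 0.071). Its change was 1.23 with a culture set term and 1.48 on the wide arrays, where a single GM-CSF+IL-6 array was left. The set term codes fresh marrow with the wide arrays, so its value leans on them too and is no separate support. On the narrow arrays the change lay below the value over all arrays. Also not called were Nos2 (0.55), Cebpb (-0.30) and S100a8 (-0.11).

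The 6 culture arrays formed sets that differed in spread. A narrow set of 4 arrays had interquartile ranges of 2.54 to 2.60, and a wide set, the third GM-CSF+IL-6 array and the second GM-CSF+G-CSF array, had 3.28 to 3.37, against 3.11 to 3.21 in fresh marrow. For GM-CSF+IL-6 the count was 2304 with a culture set term (1492 up, 812 down), 4290 on the narrow arrays (1813 up, 2477 down) and 2367 on the wide arrays (1617 up, 750 down). The direction of the majority thus turned with the set. For GM-CSF+G-CSF the counts were 2257 (1393 up, 864 down), 4080 (1702 up, 2378 down) and 2106 (1279 up, 827 down). Quantile normalisation again gave 48.9% of changed genes up with IL-6, against 35.5%, and 44.9% with G-CSF, against 32.4%.

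**Figure D5:**
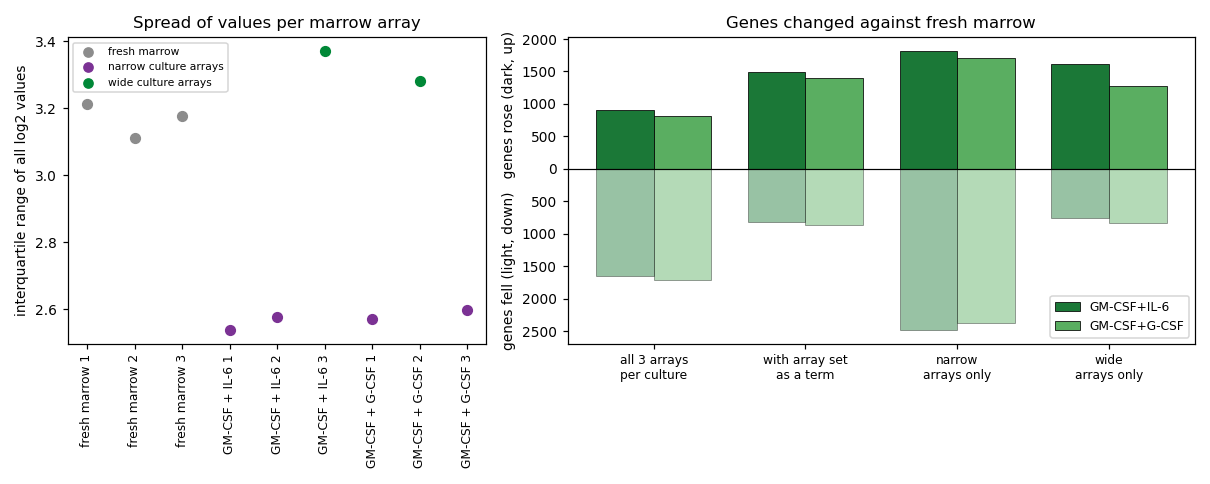
Interquartile range of each marrow array, and genes that rose or fell in each culture with all arrays, a culture set term, the narrow arrays or the wide arrays.

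Antigen presentation genes rose in 11 of 15 cases in GM-CSF+IL-6 cultures (median 1.90, adjusted p = 2.69e-10), among them the integrin Itgax (4.13), Ccr7 (3.29) and the class II genes H2-Aa (3.27) and H2-Eb1 (3.26). There were 12, 10 and 12 rises under the set term, narrow arrays and wide arrays, the order kept for the values that follow. Primary granule genes fell in 10 of 11 cases (median -2.13, adjusted p = 2.69e-10), or 9, 10 and 9 under the same settings, with Nkg7 at -4.59, Fcnb at -3.76 and Elane at -3.37. Alternative activation genes gave 8 rises and 2 falls (median 1.68, adjusted p = 0.000255, and adjusted p = 0.052 with an estimated correlation, medians 1.91, 1.52 and 2.06), with Ccl22 at 4.68 and Mgl2 at 4.06. Monocyte and macrophage genes gave 4 rises and 9 falls (median -1.07, adjusted p = 0.00139, and adjusted p = 0.0966 with an estimated correlation, medians -1.07, -0.78 and -1.06), with C1qa at -4.29. Later granule genes gave 8 falls (median -0.91, adjusted p = 7.58e-05, and adjusted p = 0.28 with an estimated correlation; medians -0.83, -0.97 and -0.82). Cytokines and chemokines gave 10 rises and 2 falls (median 1.36, adjusted p = 0.00232, and adjusted p = 0.201 with an estimated correlation; medians 1.29, 1.05 and 1.41), with Il1a at 2.08 and Osm at -3.02. Myeloid transcription factors gave 2 rises and 6 falls (median -0.80, adjusted p = 0.000961, and adjusted p = 0.369 with an estimated correlation; medians -0.34, -1.08 and -0.25), from Irf4 (2.85) to Gfi1, a factor of granulocyte maturation (-3.22). Cholesterol biosynthesis genes gave 5 rises (median 0.74, adjusted p = 0.0016, and adjusted p = 0.397 with an estimated correlation, Sqle 1.93). The settings gave 10, 4 and 9. Cell cycle genes gave 2 falls among 22 (median -0.44, adjusted p = 0.00242, and adjusted p = 0.586 with an estimated correlation, medians -0.09, -0.62 and -0.06). Interferon-stimulated genes gave 6 falls, or 7 adjusted over the list alone (median -0.65, adjusted p = 0.0147, and adjusted p = 0.535 with an estimated correlation; medians -0.25, -0.63 and -0.26). Fibroblast markers fell in 5 cases, or 6 adjusted over the list alone (median -1.08, adjusted p = 0.000546, and adjusted p = 0.213 with an estimated correlation; medians -1.48, -0.85 and -1.36). Immunosuppressive effectors did not pass (6 rises and 2 falls, median 0.55, adjusted p = 0.243; medians -0.01, 0.63 and 0.02).

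With GM-CSF and G-CSF 2520 genes changed, 816 up and 1704 down. The largest rises were again Mmp12 (8.17 ± 0.19), Ccn3 (7.31 ± 0.40), Clec4n (6.80 ± 0.19), Cxcl3 (6.11 ± 0.21), then Plet1 (5.91 ± 0.37), Ccl17 (4.91 ± 0.37), Lrp12 (4.80 ± 0.26) and Cdh1 (4.77 ± 0.47). Falls were led by Vcam1 (-7.03 ± 0.34), C1qb (-5.75 ± 0.23), the clotting factor F13a1 (-5.62 ± 0.27), Tmem45a2 (-5.54 ± 0.49), Orm1 (-5.54 ± 0.64), Apoe (-5.46 ± 0.31), Adipoq (-5.38 ± 0.16) and C1qa (-5.26 ± 0.17). Cd274 (3.36 ± 0.23), Adgre1 (1.73), Tgfb1 (1.32) and Il4ra (1.17) rose, and Ptgs2 (-4.63) and Stat3 (-1.19, or -0.68 with the set term) fell. Arg1 (0.35 ± 0.35, adjusted p = 0.42), Nos2 (0.66) and Cebpb (0.36) did not pass.

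Antigen presentation genes rose in 8 of 15 cases in GM-CSF+G-CSF cultures (median 1.38, adjusted p = 8.64e-06, and adjusted p = 0.0751 with an estimated correlation). Ccr7 rose by 3.91 and Itgax by 3.0, and the medians were 1.61, 0.98 and 1.81 under the set term, narrow and wide arrays. Primary granule genes fell in 10 of 11 cases (median -2.57, adjusted p = 1.23e-10, medians -2.30, -2.81 and -2.10), with Fcnb at -4.81. Cell cycle genes fell in 8 of 22 cases (median -0.79, adjusted p = 1.32e-06, and adjusted p = 0.356 with an estimated correlation, Mki67 -1.59, Kif11 -1.40). The number was 1, 12 and 0 under the set term, narrow and wide arrays. Cholesterol biosynthesis genes gave 4 rises (median 0.92, adjusted p = 0.000598, and adjusted p = 0.363 with an estimated correlation, Sqle 2.01), but 11, 3 and 11 under these settings. Cytokines and chemokines gave 10 rises and 1 fall (median 1.12, adjusted p = 0.000201, and adjusted p = 0.117 with an estimated correlation; medians 1.52, 1.17 and 1.32), with Il1rn at 2.35. Matrix remodelling genes gave 6 rises and 1 fall (median 0.85, adjusted p = 0.000335, and adjusted p = 0.165 with an estimated correlation; medians 1.31, 0.76 and 1.17), with the cathepsin Ctsl at 3.14 and fibronectin Fn1 at -2.92. Platelet and megakaryocyte markers gave 3 falls (median -0.82, adjusted p = 0.00692, and adjusted p = 0.337 with an estimated correlation; medians -1.10, -0.69 and -1.18). Immunosuppressive effectors did not pass (7 rises and 2 falls, median 0.50, adjusted p = 0.0634; medians 0.47, 0.56 and 0.30).

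The cultures differed from each other in 119 genes, 83 higher with IL-6 and 36 higher with G-CSF. Hormad1 (4.14 ± 0.38), Arl2bp (3.76 ± 0.20), the secreted resistin-like Retnla (3.08 ± 0.51), Asgr2 (2.75 ± 0.25) and Ccdc80 (2.50 ± 0.23) were higher with IL-6. Wfdc17 (-1.81 ± 0.24), Tnfaip8 (-1.79 ± 0.25), Ly6i (-1.79 ± 0.21), the metalloreductase Steap4 (-1.69 ± 0.31) and the noncoding RNA Neat1 (-1.57 ± 0.25) were higher with G-CSF. Antigen presentation genes were higher with IL-6 in 5 of 15 cases (median 0.84, adjusted p = 2.15e-15), or 5, 5 and 1 under the set term, narrow and wide arrays. They were Dpp4 (1.84), H2-Eb1 (1.77), H2-Aa (1.63), H2-Ab1 (1.57) and Itgax (1.12). Alternative activation genes were higher in 4 of 12 cases, or 5 adjusted over the list alone (median 0.62, adjusted p = 2.81e-09), and in 4, 3 and 1 under these settings, with Mgl2 at 2.18 and Ccl17 at 2.04. Cell cycle genes lay higher as a group though 0 passed singly (median 0.31, adjusted p = 7.32e-07, and adjusted p = 0.342 with an estimated correlation; medians 0.31, 0.29 and 0.33). No gene of the fixed panel passed, with Arg1 at 0.44 ± 0.35 (adjusted p = 0.99) and Cebpb at -0.66 ± 0.17 (adjusted p = 0.062). The count was 146 with the set term, 157 on the narrow arrays and 37 on the wide arrays. A model of these groups alone, which takes the spread from the culture arrays only, gave 2 genes. The direction of the majority turned without the third IL-6 array (50 up, 173 down) and without the first G-CSF array (46 up, 55 down).

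Cultures and tumors shared part of their changes. Of the 440 genes changed in all 4 tumors, 189 changed in the same direction in GM-CSF+IL-6 cultures. There were 82 up and 107 down (8.7 and 24.1 expected, odds ratios 18.5 and 7.14, exact p = 9.07e-60 and 3.14e-43). Of the genes that rose in the tumors 14 fell in these cultures, and of those that fell 23 rose. In GM-CSF+G-CSF cultures 199 did so, 84 up and 115 down (7.8 and 24.9 expected, odds ratios 22 and 7.83, exact p = 2.68e-66 and 7.58e-49), with 15 and 14 in the opposite direction. With housekeeping centring the overlap was 62 up and 148 down for IL-6 (29.5% up, against 43.4%) and 64 up and 150 down for G-CSF (29.9% up, against 42.2%). With the culture set term the counts were 190 and 202, on the narrow arrays 195 and 199, and on the wide arrays 186 and 193. Across genes the change in culture correlated with the mean tumor change at 0.36 for IL-6 and 0.373 for G-CSF. Genes are not independent of one another, so the exact p values overstate the evidence. Neither they nor these correlations measure the spread between arrays. Cxcl3 rose in all 4 tumors and both cultures, while Arg1, the largest shared rise of the tumors, was not called in either culture with all arrays.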

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

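The tests of the strain, of the X and Y linked share and of the other splits of the arrays were set before their results were seen, whereas the tests of autosomal genes by sex and of T and NK cells were chosen only after the results were seen. The results given first stood out because an effect differed between groups by a test of the difference itself.

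The cultures with IL-6 and with G-CSF differed in 119 genes, with list medians of 0.84 for antigen presentation genes and 0.62 for alternative activation genes. Of the 10 splits of these 6 arrays 5 gave as many genes, with 576 as the highest of the others. The other 4 such splits put both wide culture arrays on 1 side and gave 357 to 576 genes, which points to a structure of the arrays by set. The count with a culture set term was 146.

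C26-GM tumor and C26-GM spleen cells differed in 1120 genes, against 114 in the highest of the other splits. Arg1 (6.48), Ptgs2 (4.91) and Cd274 (1.01, but below 2-fold with the actin covariate) were higher in the tumor, and Cybb (-1.89) and Adgre1 (-1.41) were lower. List medians were 1.96 for interferon-stimulated genes, 1.61 for cytokines and chemokines, 0.66 for immunosuppressive effectors, -0.92 for antigen presentation genes and -2.52 for primary granule genes.

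The tumor effect differed between C57BL/6 and BALB/c models in 897 genes. Of 100 splits of the 18 arrays into the 6 groups 2 gave as many, the real one included, with 920 as the highest other. These splits mix strains, tumors and spleens. They do not test the difference of the tumor effect itself, so no conclusion on chance is drawn from them. Adgre1 (2.06), Il10 (1.97), Irf8 (1.30) and Nos2 (1.17) were more positive in C57BL/6, and Cebpb (-1.49), S100a8 (-4.05) and S100a9 (-4.34) more negative. The Nos2 difference comes from EL-4 (2.93, against 0.58 in MCA203) and was not called with housekeeping centring. That of Cebpb comes mainly from C26-GM tumor (2.62) and MCA203 (-0.16), since 4T1 (1.09) and EL-4 (0.88) lay close together. List medians were 2.83 for NK markers, 2.19 for T cell markers, 1.15 for antigen presentation genes, 0.62 for monocyte and macrophage genes and -3.38 for later granule genes. For monocyte and macrophage genes the BALB/c models went opposite ways, with medians of -1.66 in C26-GM tumor and 0.55 in 4T1. Each strain carried its own tumors, so strain and tumor type cannot be separated here. The male pattern of the C26-GM arrays enters this difference and the mean over the 4 models as well.

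For each comparison of 3 arrays with 3 the 10 splits are too few for a share under 0.05, and the real split counts as 1 of them. The real counts and the highest of the other splits were 1118 and 0 for C26-GM spleen, 2073 and 0 for C26-GM tumor, 2231 and 0 for 4T1, 1968 and 0 for EL-4 and 1897 and 0 for MCA203. They were 2560 and 869 for GM-CSF+IL-6, 2520 and 597 for GM-CSF+G-CSF and 254 and 1 for the healthy spleens. For the mean over the 4 models 1 of 100 splits, the real one, gave as many as 1500 genes, with 310 as the highest other. The other splits mix tumor models and spleens within a strain, which widens the spread and lowers their counts. No conclusion on chance is drawn from them either.

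Outside the gene measurements, the control probe sets for actin differed between 3' and 5' ends by 2.42 on the third C26-GM tumor array. Among 9160 probe sets without a gene symbol, control probe sets not counted, 216 changed the same way in all 4 tumors, 13 up and 203 down.

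The labels of the 3 healthy spleen arrays titled C57BL/6 conflict, since titles and strain entries name C57BL/6 while source and description name BALB/c. If the arrays came from BALB/c mice, strain genes should not separate them from the BALB/c spleens. Of the 254 genes that differed between the healthy spleens 203 (79.9%) differed the same way between the tumors of the 2 strains, which argues against that label. H2-Ea lay at 6.60 to 6.93 on these arrays, at 6.23 to 7.34 in the C57BL/6 tumors and at 9.35 to 13.05 on the 21 BALB/c arrays.

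The 6 C26-GM arrays had low Xist (5.15 to 6.47) and high Eif2s3y (8.11 to 8.95), against 10.06 to 11.12 and 2.16 to 2.70 on the other 24. The ranges of the Y-linked Kdm5d (3.87 to 4.70 against 2.99 to 4.24) and Uty (3.73 to 5.61 against 2.60 to 3.92) overlapped. A candidate explanation for part of the C26-GM changes is the sex of the mice, male against female references. X and Y linked genes made up 33 of 1117 changed genes in C26-GM spleen (2.95%), against 3.46% of genes tested, a ratio of 0.855. In C26-GM tumor they made up 78 of 2066 (3.78%), a ratio of 1.09, against 0.748 to 0.912 in the other tumors. The share of X and Y linked genes was thus close to that among all genes tested. With so few of them, most changed genes lie on autosomes whatever the cause. This share cannot tell whether sex acts on autosomal genes. Autosomal genes that C26-GM tumor shares with EL-4 and MCA203, whose mice match their references in these markers, numbered 469 against 60.7 for independent lists, a ratio of 7.72, which argues against sex for these genes. The other 1519 autosomal genes were not changed the same way in both EL-4 and MCA203. Some of them changed the same way in 4T1, whose arrays have the female pattern. C26-GM tumor and 4T1 shared 347 rises and 556 falls, X and Y linked genes included, against 174 and 266 in all 4 models. They have the same reference, so part of this overlap may come from it. For genes changed in C26-GM tumor alone sex and tumor cannot be told apart, since every C26-GM array has the male pattern of Xist and Eif2s3y. The GM-CSF made by this tumor stays an open biological explanation.

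T and NK genes were more positive in the C57BL/6 models. CD11b enrichment would remove T cells without CD11b but keeps NK cells, which carry it, so it does not argue against these. EL-4 is a thymoma, yet 7 T cell markers also rose in MCA203, a tumor of another origin. MCA203 tumors hold no EL-4 cells by design, so EL-4 cells are not in question for that part and no test was needed. For the EL-4 part all 6 rising T cell markers also rose in MCA203, so thymoma cells and host lymphocytes cannot be told apart there. T and NK cells in the enriched fraction are a candidate source, and the median difference of the tumor effect, C57BL/6 less BALB/c models, was 2.24 over 25 measured transcripts of such cells outside the marker lists (quartiles 0.84 to 3.05, 18 differences positive and 0 negative). Part of it comes from the BALB/c models, where 12 of the 25 fell and 2 rose in C26-GM tumor and 14 fell and 1 rose in 4T1, against 11 rises and 2 falls in EL-4 and 13 rises and 3 falls in MCA203. The transcripts did not move together, as these genes picked after the values were seen show: from C57BL/6 spleen to EL-4 and MCA203, mean Gzmb went from 6.20 to 10.79 and 11.37 and mean Thy1 from 5.74 to 9.76 and 9.28, but mean Ltb from 10.85 to 8.32 and 8.0 and mean Cd7 from 9.35 to 6.26 in both. The spleen reference may hold lymphocytes of its own, and expression in the CD11b+ cells themselves was not tested, so the source stays open.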

How the results depend on the processing

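The culture set term, the narrow and wide culture arrays, the model without the third C26-GM arrays and the actin covariate were chosen only after the results were seen. Of the counts of genes under settings other than leaving out arrays 181 stayed within 1.5 times and 22 moved, and 157 and 5 did so when arrays were left out. A model of only the compared groups gave 2 genes between the cultures, and adjusted p below 0.01 gave 65. Array weights gave 4287 genes for GM-CSF+IL-6 and 3934 for GM-CSF+G-CSF, though a fit of these weights stopped before it converged. The narrow arrays gave 4290 and 4080, and the wide arrays 37 genes between the cultures. Without a fold minimum the counts were 2627 for C26-GM spleen, 5015 for C26-GM tumor, 4613 for 4T1, 4577 for EL-4, 4338 for MCA203, 7121 and 7227 for the cultures with IL-6 and G-CSF, 226 between them, 2580 for C26-GM tumor against spleen, 465 between strains, 1428 for the difference of the tumor effect, 6513 for the mean, 1033 for all 4 tumors, and 571 and 596 for the overlaps. The counts without a fold minimum and at adjusted p below 0.01 moved because the calling rule itself changed. The cause of the other moves was not tested.

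Leaving out each array in turn gave 1033 to 1232 genes for C26-GM spleen, 2011 to 2247 for C26-GM tumor, 2142 to 2325 for 4T1, 1844 to 2025 for EL-4 and 1778 to 1921 for MCA203. The range was 2214 to 4288 for GM-CSF+IL-6, highest without the third IL-6 array, and 2223 to 4075 for GM-CSF+G-CSF, highest without the second G-CSF array. Between the cultures it was 64 to 225: 64 without the third G-CSF array, 225 without the second (207 up, 18 down) and 223 without the third IL-6 array (50 up, 173 down), and without the first G-CSF array 46 were up and 55 down. It was 1047 to 1247 for C26-GM tumor against spleen, 196 to 234 between strains, 777 to 948 for the difference of the tumor effect, 1464 to 1531 for the mean, 416 to 451 for all 4 tumors, and 174 to 196 and 185 to 205 for the overlaps.

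With a replicate block the counts were 1114, 2067, 2229, 1966 and 1894 for the tumor comparisons in that order, 2559, 2521 and 114 for the cultures, 1119 for C26-GM tumor against spleen, 248, 875 and 1500 for strain, difference and mean, 436 for all 4 tumors and 187 and 197 for the overlaps. Of 167 gene lists called 56 held with an estimated correlation, with 111 lost and 0 gained. Housekeeping centring lost 7 and gained 9 (169 called), and the replicate block lost 0 and gained 1 (168 called). The fry test, which sets a list against no change and not against the other genes, called 164, with 14 of the 167 not called and 11 others called. For named genes 8073 calls were the same, 219 were lost and 18 gained when arrays were left out. Under the other settings 11513 were the same, 260 were lost, 32 were gained and 1 reversed: Klrk1 in GM-CSF+G-CSF was -0.01 on the wide arrays (adjusted p = 0.988). Housekeeping centring moved the median of all genes from -0.010 to -0.297 in 4T1, from 0.015 to -0.343 in EL-4, from 0.140 to -0.108 in MCA203, from 0.091 to -0.069 in C26-GM spleen, from 0.005 to 0.194 for C26-GM tumor against spleen, from 0.124 to 0.019 and from 0.140 to 0.030 in the cultures, from 0.029 to -0.145 for the difference and from 0.077 to -0.139 for the mean.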

Other observations

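The test with a culture set term and those within culture sets were chosen only after the results were seen. Erythroid markers fell in 6 of 7 cases in C26-GM tumor (median -1.57, adjusted p = 0.000163, and adjusted p = 0.155 with an estimated correlation), in 5 in 4T1 (median -1.73, adjusted p = 0.000117, and adjusted p = 0.148 with an estimated correlation) and in 4 in EL-4 (median -1.22, adjusted p = 9.29e-05, and adjusted p = 0.141 with an estimated correlation). In MCA203 they fell in 3 cases (median -0.36, adjusted p = 0.0206, and adjusted p = 0.389 with an estimated correlation). Markers of mast cells, basophils and eosinophils gave 5 falls in C26-GM tumor (median -1.13, adjusted p = 1.72e-05, and adjusted p = 0.077 with an estimated correlation). They gave 5 falls in 4T1, or 6 adjusted over the list alone (median -1.13, adjusted p = 1.16e-05, and adjusted p = 0.0712 with an estimated correlation). In EL-4 they gave 1 rise and 3 falls (median -0.54, adjusted p = 0.0115, and adjusted p = 0.313 with an estimated correlation), and in MCA203 4 falls (median -0.68, adjusted p = 7.75e-06, and adjusted p = 0.0662 with an estimated correlation). The platelet chemokine Pf4 rose in 4T1 (3.88) and EL-4 (4.82), though platelet markers as a group did not pass there as they did in C26-GM spleen (medians -0.15 and 0.09, mean 0.47 in 4T1). The platelet call in C26-GM spleen was itself lost with an estimated correlation.

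In the cultures, B cell markers fell in 3 of 10 cases with IL-6 (median -0.75, adjusted p = 0.00916, and adjusted p = 0.169 with an estimated correlation), erythroid markers in 3 of 7 (median -0.74, adjusted p = 0.0204, and adjusted p = 0.389 with an estimated correlation) and platelet markers in 3 of 9 (median -0.79, adjusted p = 0.0148, and adjusted p = 0.384 with an estimated correlation). With G-CSF fibroblast markers fell in 6 cases, or 7 adjusted over the list alone (median -1.06, adjusted p = 0.000238, and adjusted p = 0.187 with an estimated correlation). With the culture set term these medians were -0.71, -1.10, -0.92 and -1.46, on the narrow arrays -0.61, -0.55, -0.74 and -1.10, and on the wide arrays -0.80, -1.12, -0.87 and -1.49. The probe sets of some named genes moved apart, Itgb2l from -2.76 to 0.84 with IL-6 and from -2.91 to 0.74 with G-CSF, Loxl1 from -1.08 to 0.68 with IL-6 and Dcn from -1.66 to 0.51 with G-CSF. Other named genes had a probe set near no change. Examples were Stat3 (-2.48 to 0.30 with IL-6, -2.51 to 0.27 with G-CSF), Nt5e in 4T1 (0.20 to 6.18) and Prf1 in the difference of the tumor effect (-0.14 to 5.03).

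Comparisons that share a control shared many calls. EL-4 and MCA203 rose together in 512 genes and fell together in 575 (58.5 and 43.4 for independent lists), with 16 in opposite directions, and their changes correlated at 0.728 across genes, against 0.499 in simulation from shared controls alone. C26-GM tumor and 4T1 shared 347 rises and 556 falls (52.9 and 70.6 for independent lists) with 62 opposite (correlation 0.536, simulated 0.501). C26-GM spleen and tumor shared 257 and 524 with 20 opposite (0.716, simulated 0.498). The cultures shared 619 and 1346 with 0 opposite (0.942, simulated 0.501). A shared control of equal size gives a simulated correlation near 0.5 whatever the spread, so these correlations alone do not gauge the agreement. The covariances were 0.401 for EL-4 with MCA203 (simulated 0.0272) and 0.347 for C26-GM tumor with 4T1 (simulated 0.0274). They were 0.325 for C26-GM spleen with tumor (simulated 0.0272) and 0.605 for the cultures (simulated 0.0274). Among all 18194 genes, whether changed or not, the arrays of the compared groups did not overlap in 7188 for C26-GM spleen, 9221 for C26-GM tumor, 9681 for 4T1, 9142 for EL-4 and 9463 for MCA203, where chance gives 10%. The number was 6663 for GM-CSF+IL-6, 7384 for GM-CSF+G-CSF, 4667 for C26-GM tumor against spleen and 4984 between strains. Between the cultures it was 1154, below what chance gives.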
